A study of Mus musculus with 23 samples.

How the data were processed

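Hippocampal RNA was measured in 23 mouse libraries, 11 from wild-type (WT) animals and 12 labelled as knockout of Nrsn2, which encodes neurensin 2, a small neuronal membrane protein. Animals were either controls or had gone through 10 days of chronic social defeat stress (CSDS), in which a mouse meets a new aggressive CD-1 mouse for 5 min each day and is then housed behind a perforated divider. Per the labels' protocols, RNA was extracted with a lipid tissue kit, libraries were made with the TruSeq RNA V2 kit, which selects poly(A) RNA and does not keep strand, and 75 bp single-end reads were sequenced. Per the submitters' processing notes, reads were aligned with STAR to mm10. The STAR version, the gene annotation and the counting tool are not given in the sources used here, so genes that overlap, near-identical copies and antisense partners are reported as uncertain.

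One table per genotype was deposited, with 39017 genes in each. The authors deposited RPKM values (reads per kilobase of gene, scaled to the size of the library) for every library, along with their mean RPKM per group. Per the file headers, the authors also deposited log2 fold changes and a mean log2 abundance, which was identical in both tables for the 17840 genes they tested. A likelihood ratio score and a p-value with its false discovery rate complete the authors' deposited table, and the headers name edgeR. Every column of library values could be assigned to a sample by its name. Genes were named as in the tables, where 1322 had no symbol. Of the gene identifiers, 37607 were found in a GENCODE mouse annotation and 37570 (96.3%) had the same coordinates there, so all coordinates are printed as deposited, in mm10.

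The title and the treatment field gave the same condition for 20 libraries, 5 in each of 4 groups (WT control, WT CSDS, knockout-labelled control, knockout-labelled CSDS). For 3 libraries they did not: WT 9B and knockout-labelled 11 and 10B are titled control but carry CSDS in the treatment field. These 3 were left out of the 5 comparisons across genes. They entered the test of Nrsn2, which needs only the genotype, the alternative settings, and single values. The authors' mean control RPKM averages them with the controls, since the mean over all libraries titled control differed from the deposited mean by at most 4.0e-06 in the WT table and 5.7e-06 in the other. The labels do not say whether the libraries of a group came from separate animals beyond giving each a number, so p-values measure the spread between these samples.

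Depth was estimated from low values of 11945 single-exon genes, where RPKM is a whole multiple of what 1 read is worth. The libraries came to 25.62 to 55.63 M reads, median 44.65 M. With those depths 92.7 to 94.0% of the values used were within 0.05 of a whole read. The 10 genes of highest RPKM took 19.1 to 23.4% of the RPKM of a library.

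Values were tested as log2(RPKM + 0.5), for genes with a mean RPKM of at least 0.5 over the libraries fitted, with limma-trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. The 5 comparisons were CSDS against control in WT, CSDS against control in libraries labelled knockout, the difference of these effects (knockout label minus WT), and knockout label against WT among controls and after CSDS. The last 3 were run across both tables because the values are RPKM for the same genes with the same lengths. The WT and knockout-label comparisons share no library, while the other 3 reuse the same libraries. For Nrsn2 a two-sided permutation test with 100000 resamples was used. All means are given with the SD and log2 fold changes with the SE, n = 5 libraries per group unless stated.

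Before the data were examined, 36 gene lists were fixed for pathways, hippocampal cell types, neighbouring tissue and blood. In each comparison the members past adjusted p = 0.05 over all genes were counted, and again adjusted over the list alone. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the 36 lists. Of 851 list genes, 848 were in the tables. Lists overlap in some members, such as Igf2 and Pdgfra. The text describes the lists of most weight in each comparison.

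The rule for named genes was also fixed before the data were examined. It takes Nrsn2, the 12 highest and 12 lowest fold changes among genes past adjusted p = 0.05 with mean RPKM of at least 1 and every library of a group beyond the mean of the other, the 4 members of smallest p from each list described, and 12 stress genes wherever measured (Fkbp5, Sgk1, Fos, Arc, Npas4, Bdnf, Gria1, Gria2, Nr3c1, Nr3c2, Ttr and S100a10). For the difference of effects the condition on single libraries has no meaning and was not applied. Gene models without a name were counted and not named. Some genes that the rule takes are not reported here, in text or plots. Names outside this rule are said to be chosen after their values were seen.

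Alternatives were other pseudocounts, filters, scalings (median ratio, quantile), variance models, a choroid plexus covariate, the number in the titles as a block, the 3 libraries of conflicting label added either way, each library left out in turn, and the authors' deposited edgeR test. Removing GC and length trends, limma-voom on reads rebuilt from RPKM, and leaving out both control libraries with high Xist were chosen after seeing the data.

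The test was checked on simulated data with 200 genes changed, 50 for each fold, at the spread of the real libraries. Noise was drawn independently for each gene and library, so effects that many genes of a library share were not simulated. The shares of false calls below hold for that setting and do not measure errors in the real data. At folds of 1.25, 1.5, 2 and 4, it recovered 78, 90, 96 and 100% in WT, where 11 of 193 calls were false. The knockout-label setting recovered 72, 88, 94 and 100%, with 11 of 188 calls false, and the difference of effects 48, 88, 98 and 100%, with 8 of 175 false. For the genotype comparisons the shares were 60, 90, 96 and 100% among controls (10 of 183 false) and 74, 98, 92 and 100% after CSDS (8 of 190 false). Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads and values per exon were not analysed here.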

Results

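The series measured gene expression in the mouse hippocampus at baseline and after 10 days of social defeat, in WT mice and in mice labelled as lacking Nrsn2. The comparisons below use 5 WT control, 5 WT CSDS, 5 knockout-labelled control and 5 knockout-labelled CSDS libraries. Estimated depth was 36.76 to 55.63 M reads per library in WT controls and 37.72 to 52.77 M in WT after CSDS. The corresponding ranges were 25.62 to 52.29 M and 37.03 to 50.42 M for the knockout label. Control 10 of each genotype had high Xist, which marks females, and little of the Y-linked gene Ddx3y. No CSDS library had this pattern, so sex was not balanced in the CSDS comparisons. Both genes were chosen after their values were seen.

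The target gene came first, as a check of the genotype labels. Nrsn2 (ENSMUSG00000059361, chromosome 2, 152368755 to 152376638, mm10) was not lower in libraries labelled knockout. Its level was 29.1 ± 2.42 RPKM in WT controls, 29.7 ± 2.55 in WT after CSDS, 31.2 ± 1.93 in knockout-labelled controls and 34.1 ± 2.34 in knockout-labelled libraries after CSDS (SD, n = 5 each). Over all libraries the mean was 32.9 ± 2.37 RPKM in 12 labelled knockout, range 28.0 to 37.4, against 29.5 ± 2.25 in 11 WT, range 25.3 to 33.3. The ratio was 1.11 (two-sided permutation p = 0.0022, and p = 0.0083 without the 3 libraries of conflicting label). These are values for the whole gene. The labels do not describe the allele, and values per exon were not analysed here, so the level neither shows nor excludes loss of the protein. The term "libraries labelled knockout" is kept throughout for this reason, and every direction between genotypes below rests on that label.

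**Figure D1:**
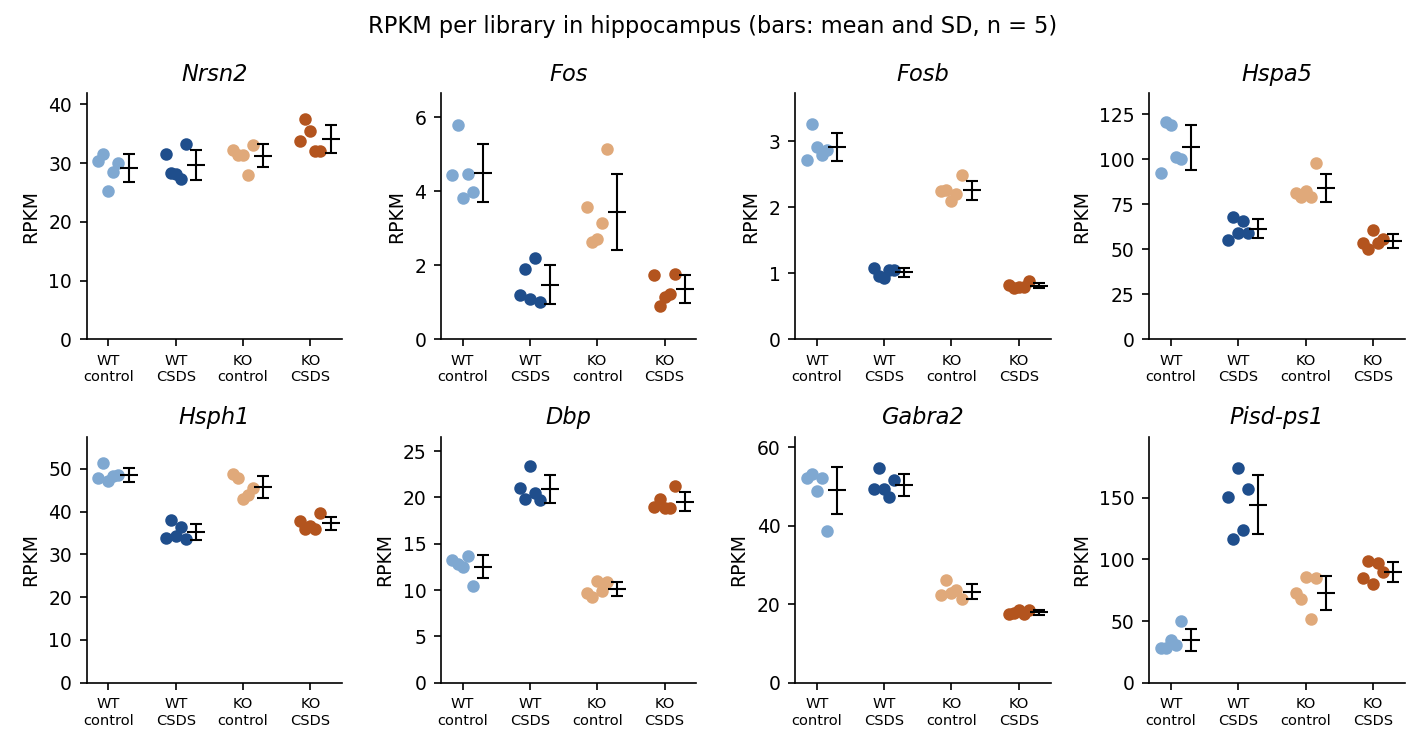
RPKM of Nrsn2, Fos, Fosb, Hspa5, Hsph1, Dbp, Gabra2 and Pisd-ps1 in each of the 20 libraries, with group mean and SD (n = 5 per group). Fosb fell from 2.91 to 1.01 RPKM in WT and from 2.26 to 0.811 in libraries labelled knockout, while Nrsn2 stood between 25.3 and 37.4 RPKM in all of them.

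The first comparison asked what repeated defeat changes in the WT hippocampus. Genes that neurons switch on within minutes of activity were lower after CSDS. Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), a component of the AP-1 transcription factor, fell from 2.91 ± 0.208 to 1.01 ± 0.0667 RPKM (log2 fold change −1.17 ± 0.05, limma adjusted p = 7.15e-06). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), which encodes another component of AP-1, fell from 4.50 ± 0.778 to 1.47 ± 0.531 RPKM (−1.37 ± 0.17, adjusted p = 0.000818). The synaptic scaffold gene Homer1 changed by −0.81 ± 0.07, Gadd45b by −0.55 ± 0.04, Fosl2 by −0.48 and Arc, which acts in AMPA receptor removal, by −0.45 ± 0.10 (adjusted p = 0.0106). Of 26 immediate early genes measured, 19 fell and none rose, and 20 fell adjusted over the list alone (camera adjusted p = 4.27e-10; adjusted p = 0.257 with an estimated correlation). Npas4 (−0.38, adjusted p = 0.0576) and Bdnf (0.10, adjusted p = 0.133) did not pass.

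Chaperone genes were lower in WT after CSDS as well. Of 19 heat shock and chaperone genes, 18 fell, also adjusted over the list alone, with a median log2 fold change of −0.29 (camera adjusted p = 3.27e-13; adjusted p = 0.257 with an estimated correlation). Hsph1, a large cytosolic chaperone, fell by 0.46 on the log2 scale (SE 0.04), the HSP90 cofactor gene Chordc1 by 0.44, Hsp90aa1 by 0.33 and Ahsa1, an activator of HSP90, by 0.23. Among 23 genes of endoplasmic reticulum stress, 18 fell and 1 rose, 20 and 1 adjusted over the list alone (camera adjusted p = 1.98e-10; adjusted p = 0.257 with an estimated correlation). Hspa5 (chromosome 2, 34771970 to 34777547), the main chaperone of the endoplasmic reticulum, went from 107 ± 12.5 to 61.3 ± 5.30 RPKM (−0.79 ± 0.08, limma adjusted p = 0.000403). The disulfide isomerase gene Pdia6 changed by −0.54, Xbp1, a transcription factor of the unfolded protein response, by −0.53 and Hsp90b1 by −0.46.

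The WT genes that rose most included copies that share reads. Pisd-ps1 (ENSMUSG00000082286, chromosome 11, 3125904 to 3131004), a pseudogene of the phosphatidylserine decarboxylase gene Pisd, rose from 34.5 ± 9.11 to 144 ± 23.8 RPKM (2.07 ± 0.16, limma adjusted p = 0.000138), and Pisd-ps2 rose by 1.91 ± 0.15. How reads were split among Pisd and its copies is not known. Other increases were Zfp982 (1.68 ± 0.28), the gastrokine gene Gkn3 (1.37 ± 0.17, adjusted p = 0.000871), Wdfy1 (0.96 ± 0.09, adjusted p = 0.000289), Mir6901 (0.99) and Rbm3os (0.96 ± 0.12), which overlaps the cold-induced gene Rbm3 on the X chromosome and cannot be told from it without strand. Zfp982 lies in a region of chromosome 4 where genotype differences gather, and a strain variant behind its rise cannot be told from defeat here. In libraries labelled knockout, Pisd-ps1, Pisd-ps2 and Wdfy1 changed by 0.32, 0.32 and 0.14. Whether a strain difference between the WT groups plays a part in their rise was not tested. Among decreases were Alox12b (−0.99), Zfp125 (−1.30) and Mir132 (−1.48 ± 0.34), which encodes an activity-induced microRNA. Haemoglobin genes, which mark red blood cells, rose in WT: Hbb-bs from 58.7 ± 9.36 to 259 ± 234 RPKM (1.82 ± 0.39, adjusted p = 0.00857), Hbb-bt by 1.80, Hba-a2 by 1.72 and Hba-a1 by 1.71, with Alas2, the first enzyme of haem synthesis in red cells, by 1.29. Of 7 red blood cell genes, 5 rose, also adjusted over the list alone, with a median of 1.71 (camera adjusted p = 0.0027; adjusted p = 0.616 with an estimated correlation). The median was 1.27 without WT CSDS 3, the library of highest haemoglobin, and with WT 9B added as CSDS the calls on this list were lost.

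Some structural RNAs, which carry no poly(A) tail, were lower in WT after CSDS. The 5.8S ribosomal RNA n-R5-8s1 changed by −2.14 ± 0.40, the U1 RNA Rnu1a1 by −1.56, the signal recognition particle RNAs Rn7s1, Rn7s2 and Rn7s6 by −1.15, −1.14 and −1.13, the 7SK RNA Rn7sk by −1.12 and the mitochondrial glycine tRNA mt-Tg by −1.22 ± 0.09. In libraries selected for poly(A) RNA, which molecules gave the reads on these genes and on microRNA genes is not known. Averaged over 7 structural RNAs, chosen after their values were seen, the log2 level was 3.75 ± 0.55 in WT controls and 2.45 ± 0.17 in WT after CSDS, and 4.11 ± 0.92 and 2.55 ± 0.15 for the knockout label. The average was lower in the same groups as the immediate early, heat shock and endoplasmic reticulum stress genes in both genotypes.

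Several groups rose by small amounts in WT. Of 68 nuclear genes of the mitochondrial respiratory chain, 28 rose and 1 fell, 37 and 1 adjusted over the list alone, with a median of 0.09 (camera adjusted p = 1.5e-11; adjusted p = 0.257 with an estimated correlation). Sdhb of complex II rose by 0.21 ± 0.02, and the complex I genes Ndufa13, Ndufs8 and Ndufs3 by 0.17, 0.16 and 0.12. Of 77 ribosomal protein genes 19 rose, 25 adjusted over the list alone (camera adjusted p = 2.8e-08; adjusted p = 0.616 with an estimated correlation), among them Rpl7a (0.20) and Rpl35 (0.16). Cholesterol synthesis genes rose in 8 of 24 cases, 11 adjusted over the list alone (camera adjusted p = 0.000272; adjusted p = 0.616 with an estimated correlation), with lanosterol synthase Lss at 0.32 ± 0.05 and Insig1 at 0.25. Of 22 microglial genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.00071; adjusted p = 0.616 with an estimated correlation). They included the purinergic receptor gene P2ry12 (0.46 ± 0.06), the lysosomal gene Cd68 (0.37) and P2ry13 (0.24). Of the other glial lists only the astrocyte list passed with camera. Of 23 astrocyte genes 6 rose and 1 fell (camera adjusted p = 0.0402, and 0.616 with an estimated correlation). Of 14 oligodendrocyte precursor genes 3 rose and 1 fell (camera adjusted p = 0.0898). Of 25 myelin genes 5 fell and 0 rose (camera adjusted p = 0.0542). Over all genes 4093 of 18274 were called, so these counts alone do not set the lists apart. With the WT library of conflicting label as CSDS, 2 astrocyte genes and 1 precursor gene were called higher, and the lower calls on these lists were lost.

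Glucocorticoid targets moved down rather than up in WT. Of 29 such genes 9 fell, also adjusted over the list alone, and none rose (camera adjusted p = 0.0071; adjusted p = 0.616 with an estimated correlation). Cdkn1a, an inhibitor of the cell cycle, changed by −0.88 ± 0.11, Ddit4 by −0.42, Klf9 by −0.28, Errfi1 by −0.24 and the glucocorticoid receptor co-chaperone gene Fkbp5 by −0.23 ± 0.06 (limma adjusted p = 0.0182). The receptor genes Nr3c1 (0.01) and Nr3c2 (0.00) and the target Sgk1 (0.03) did not pass. Clock genes moved both ways: of 18, 6 rose and 4 fell, 6 and 5 adjusted over the list alone (camera adjusted p = 0.321). Dbp (chromosome 7, 45705088 to 45710203), a transcription factor driven by the clock, rose from 12.5 ± 1.26 to 20.9 ± 1.5 RPKM (0.72 ± 0.07, adjusted p = 0.00032), the repressor Ciart rose by 0.70 ± 0.09, Nfil3, which opposes Dbp, fell by 0.68, Cry2 rose by 0.25, and Arntl and Clock fell by 0.23 and 0.24.

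Synaptic genes moved both ways in WT, and on some lists more fell than rose. That was also so over all genes, where 1806 of 18274 were called higher and 2287 lower. Of 30 AMPA receptor subunits and partners, 6 rose and 6 fell, 6 and 7 adjusted over the list alone (camera adjusted p = 0.442). Nptx1, which clusters AMPA receptors, changed by −0.45 ± 0.04, the auxiliary subunit genes Cacng2 and Shisa6 by −0.30 and −0.29, and Cpt1c by 0.15. The subunit genes Gria1 (0.01) and Gria2 (−0.11, adjusted p = 0.15) did not pass. Of 18 NMDA and metabotropic glutamate receptor genes 1 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0542, fry adjusted p = 0.0343; adjusted p = 0.616 with an estimated correlation), with the metabotropic receptor genes Grm4 at −0.36 ± 0.08, Grm5 at −0.23 and Grm7 at −0.19. Of 28 synaptic vesicle and release genes 4 fell and 0 rose, also adjusted over the list alone, where 2 rose and 7 fell at an unadjusted p under 0.05 (camera adjusted p = 0.268). They were the vesicular glutamate transporter gene Slc17a6 (−0.47 ± 0.10), Syt4 (−0.33), the active zone gene Bsn (−0.32) and Syn2 (−0.10). Of 27 neuropeptide and receptor genes of stress circuits 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.866), with the neuropeptide gene Crh at −0.55 ± 0.10 and the receptor gene Npy1r at 0.29 ± 0.05. The choroid plexus transcript Ttr differed by 1.68 ± 1.30 (adjusted p = 0.382), with WT control 6 at 16.9 RPKM against 1476 to 4740 in the other controls, and S100a10 (0.04) and Nrsn2 (0.03, adjusted p = 0.797) did not pass.

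In all, 4093 of 18274 genes passed in WT (limma-trend, adjusted), 1806 higher and 2287 lower, of which 185 differed by at least 1.5-fold and 49 by at least 2-fold. Of the 36 lists, 14 passed with camera, 11 with fry, and 0 with camera and an estimated correlation, where 5 had an unadjusted p under 0.05. The authors' deposited table has 3739 genes at a false discovery rate under 0.05, 1633 higher and 2106 lower after CSDS, and 3106 genes are common to both. With WT 9B counted as CSDS, as its treatment field has it, 1240 genes passed, and 13 immediate early, 14 heat shock and 13 endoplasmic reticulum stress genes fell and 1 respiratory chain gene rose. Other lists lost calls as well, with 8 ribosomal protein, 3 cholesterol synthesis, 1 microglial and 4 clock genes higher and 6 glucocorticoid targets and 2 clock genes lower. On the synaptic lists 2 AMPA receptor genes were higher, and 3 AMPA, 1 NMDA or metabotropic receptor and 1 vesicle gene lower, and on the stress circuit list 1 was higher and 1 lower.

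The next comparison asked the same of libraries labelled knockout. Immediate early genes were lower after CSDS here too. Fosb fell from 2.26 ± 0.147 to 0.811 ± 0.0415 RPKM (−1.07 ± 0.05, limma adjusted p = 9.77e-06), Fos by 1.07 on the log2 scale (SE 0.18, adjusted p = 0.0045), Gadd45b by 0.63, Homer1 by 0.59 and Fosl2 by 0.42. Of 26 genes on the list, 11 fell and 1 rose, 15 and 1 adjusted over the list alone (camera adjusted p = 7.8e-08; adjusted p = 0.461 with an estimated correlation). Heat shock genes fell in 12 of 19 cases, 15 adjusted over the list alone, with a median of −0.20 (camera adjusted p = 1.39e-08; adjusted p = 0.461 with an estimated correlation), including Chordc1 (−0.40), Hsph1 (−0.29), Hsp90aa1 (−0.22) and Dnaja1 (−0.20). Of 23 endoplasmic reticulum stress genes 13 fell and 1 rose, 17 and 1 adjusted over the list alone (camera adjusted p = 1.48e-08; adjusted p = 0.461 with an estimated correlation), with Hspa5 at −0.61 ± 0.06, Pdia6 at −0.45, Xbp1 at −0.41 and Hsp90b1 at −0.34. Of the structural RNAs, n-R5-8s1 changed by −2.88 ± 0.57, Rnu1a1 by −1.83, Rn7sk by −1.69 ± 0.31 and Rmrp by −1.26, while Rn7s1 (−1.13, adjusted p = 0.0574), Rn7s2 (−1.13), Rn7s6 (−1.02) and mt-Tg (−0.15, adjusted p = 0.314) did not pass. Neither Arc (−0.28, adjusted p = 0.293) nor Npas4 (−0.25, adjusted p = 0.193) nor Bdnf (0.06, adjusted p = 0.308) passed.

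Clock output was higher after CSDS in libraries labelled knockout. Dbp rose from 10.2 ± 0.746 to 19.5 ± 1.02 RPKM (0.91 ± 0.05, limma adjusted p = 2.77e-05) and Ciart rose by 0.94 ± 0.08 (adjusted p = 0.000252), with Cry2 at 0.28, Bhlhe41 at 0.27 and Per1 at 0.24, while Nfil3 (−0.59), Arntl (−0.31) and Clock (−0.20) fell. Of 18 clock genes 9 rose and 3 fell, 9 and 4 adjusted over the list alone (camera adjusted p = 0.00165; adjusted p = 0.589 with an estimated correlation). Rbm3os, which overlaps Rbm3, rose by 0.93 ± 0.09. Further increases were Lbhd2 (1.49 ± 0.33), Mir709 (1.27), Mir491 (1.12), the phospholipase gene Pla2g4e (0.91), the incretin receptor gene Glp1r (0.89 ± 0.18), the Wnt ligand gene Wnt9a (0.85), Mir129-1 (0.84), Zic1 (0.81) and Muc3a (0.77). Among decreases were Mir132 (−1.53), Mir6236 (−1.04), Itih2 (−0.94) and Dio3 (−1.0 ± 0.08, adjusted p = 0.000218), the deiodinase that inactivates thyroid hormone.

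Markers of the meninges and of vessels were lower after CSDS in libraries labelled knockout. Of 21 fibroblast genes 9 fell, 12 adjusted over the list alone, with a median of −0.66 (camera adjusted p = 1.44e-06; adjusted p = 0.62 with an estimated correlation). The GABA transporter gene Slc6a13, which marks the meninges, changed by −1.38 ± 0.25, Aldh1a2, a retinoic acid synthesis gene, by −0.94, the connexin gene Gjb2 by −0.86, and the matrix proteoglycan genes Dcn and Lum by −0.79 ± 0.07 and −0.72. Of 25 endothelial genes 10 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000107; adjusted p = 0.62 with an estimated correlation), with the tight junction gene Cldn5 at −0.82 ± 0.10, Slc16a1 at −0.41, Cdh5 at −0.38 and Pecam1 at −0.32. Interferon and antigen presentation genes fell in 7 of 26 cases, 10 adjusted over the list alone (camera adjusted p = 2.62e-06; adjusted p = 0.62 with an estimated correlation), among them H2-D1 (−0.35), B2m (−0.29) and H2-T23 (−0.28). That last count ranged from 1 to 14 over the alternative settings.

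Among neuronal genes, 5 of 20 in the GABA list rose and 1 fell, 7 and 1 adjusted over the list alone (camera adjusted p = 0.00165; adjusted p = 0.62 with an estimated correlation). Gad2 and Gad1, the GABA synthesis enzymes, rose by 0.31 and 0.26 ± 0.03 and the extrasynaptic subunit gene Gabrd by 0.28, while the subunit gene Gabra2 fell by 0.36 (SE 0.05). Gabra2 also differed strongly between genotypes, and whether strain background plays a part in its fall was not tested. Of 30 AMPA receptor genes 7 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.181), with Cacng5 at 0.71, Syndig1 at 0.32 and Nptx1 at −0.46. Glucocorticoid targets fell in 7 of 29 cases and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0337; adjusted p = 0.725 with an estimated correlation), with Angptl4 at −0.78, Cdkn1a at −0.77, Gjb6 at −0.55 and Pdk4 at −0.38. For the remaining stress genes the test was not passed: S100a10 (−0.22, adjusted p = 0.134), Nrsn2 (0.12, adjusted p = 0.149), Fkbp5 (−0.12, adjusted p = 0.286), Gria2 (−0.07), Nr3c1 (−0.06), Sgk1 (−0.05), Gria1 (0.01), Nr3c2 (0.01) and Ttr (−0.16, adjusted p = 0.908).

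In libraries labelled knockout 2747 of 18259 genes passed (limma-trend), 1126 higher and 1621 lower. The share of higher calls was 41.0%, and 49.3% after median-ratio rescaling and 52.4% after quantile normalization, so the balance of directions depends on the scaling. Of the lists 12 passed with camera, 7 with fry and 0 with camera and an estimated correlation, where 3 had an unadjusted p under 0.05. The authors' deposited table lists 3055 genes with a false discovery rate under 0.05, 1508 higher and 1547 lower, with 2101 common to both. With libraries 11 and 10B counted as CSDS, 143 genes passed, the calls on the immediate early, heat shock and glucocorticoid lists were lost and 1 endoplasmic reticulum stress gene was lower. Under that setting 2 clock, 1 GABA and 2 AMPA receptor genes were higher, and 7 fibroblast, 2 endothelial and 1 interferon gene lower. With both libraries counted as control, 13 immediate early, 15 heat shock and 15 endoplasmic reticulum stress genes were lower. In that setting 5 fibroblast, 8 endothelial and 2 interferon genes were lower. Marker values of these libraries are given under other observations. Without CSDS 4 the count was 1658. Respiratory chain and ribosomal protein genes depended on control 10: 1 and 2 rose with it, 27 and 46 without it.

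The CSDS effects in both genotypes went the same way for most genes. Over 18089 genes the log2 fold changes had a Pearson r of 0.431 and a Spearman rho of 0.51 across genes, which are not independent replicates, and 71.5% had the same sign. Genes higher in both numbered 598, against 111.3 for independent lists, those lower in both 927, against 203.6, and 10 were called in opposite directions. Of the 5277 genes called in either genotype 89.7% had the same sign. The 2 effects share no library.

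**Figure D2:**
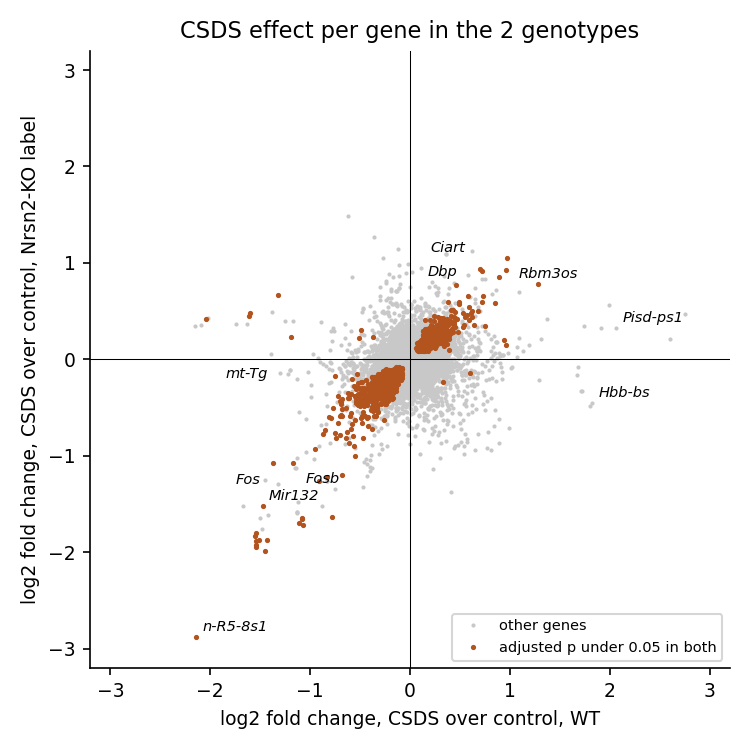
Log2 fold change of CSDS over control in libraries labelled knockout (vertical) against WT (horizontal), a point per gene, with genes past adjusted p = 0.05 in both in brown. Across 18089 genes Pearson r was 0.431, with 598 genes higher and 927 lower in both.

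**Figure D3:**
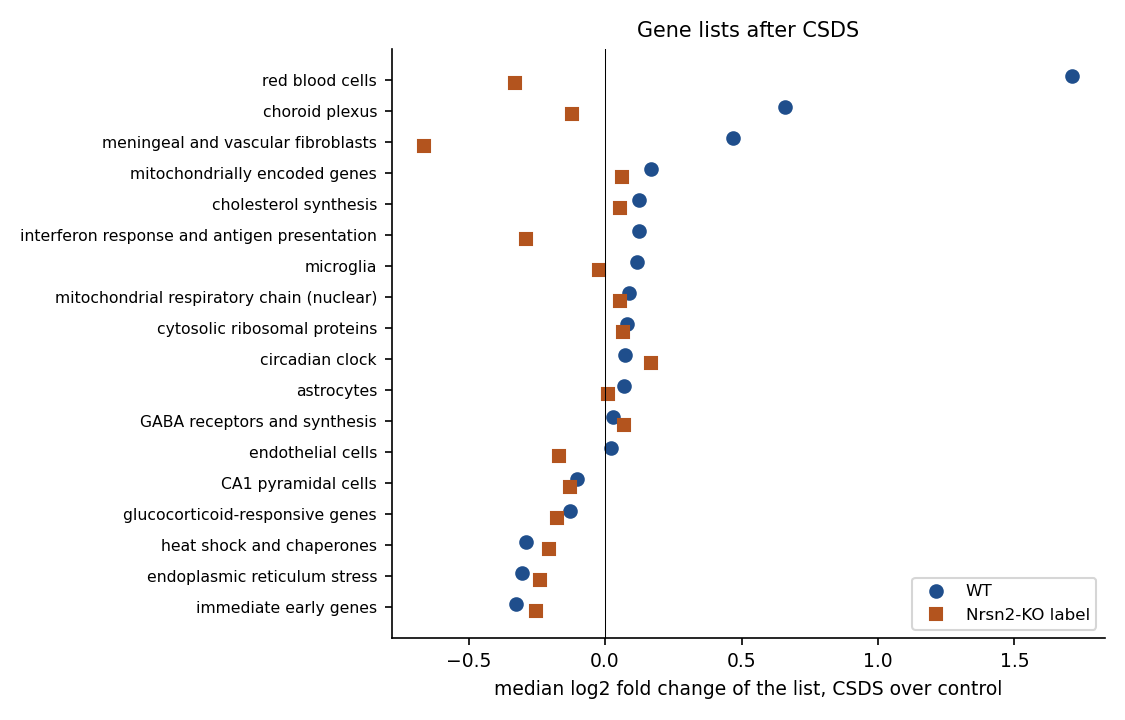
Median log2 fold change of CSDS over control for gene lists in WT (circles) and in libraries labelled knockout (squares). Heat shock genes stood at −0.29 and −0.20, while red blood cell genes were at 1.71 in WT and −0.33 for the knockout label.

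The difference of the CSDS effects asked where the genotypes responded unequally. It passed for 27 of 18263 genes (limma-trend interaction, 11 positive and 16 negative, knockout label minus WT), with 2092 at an unadjusted p under 0.05. All 27 had passed in WT and 6 had passed in libraries labelled knockout, and in all 27 the effect was larger in WT, with median sizes of 0.60 and 0.14 on the log2 scale. Pisd-ps1 was at 34.5, 144, 72.8 and 90.0 RPKM in WT control, WT CSDS, knockout-label control and knockout-label CSDS, a difference of −1.74 ± 0.22 (limma adjusted p = 0.000532), with Pisd-ps2 at −1.59 ± 0.19 and Pisd at −0.71 ± 0.09. Zfp982 was at 0.344, 2.00, 1.90 and 1.79 RPKM in the same order (−1.77 ± 0.34, adjusted p = 0.045), and Mfap2, an elastic fibre gene, at 1.82, 3.16, 3.10 and 2.66 (−0.86 ± 0.11, adjusted p = 0.00088). For both genes the WT controls stood apart from the other 3 groups. Wdfy1, an adaptor of Toll-like receptor signalling, was high in WT after CSDS, at 3.89, 8.09, 3.80 and 4.25 RPKM (−0.81 ± 0.10), and mt-Tg was low there, at 243, 104, 315 and 285 RPKM (1.07 ± 0.14). Whether a strain difference between the WT groups plays a part for Wdfy1, mt-Tg or Pisd and its copies was not tested.

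Other genes with a more negative effect in libraries labelled knockout were the smooth muscle gene Tagln (−1.20 ± 0.24), the interferon-induced Ifit3b (−0.86 ± 0.17), Adi1 of methionine salvage (−0.74 ± 0.09), Arhgef19 (−0.73 ± 0.12), Olfml3 (−0.52 ± 0.08) and Sfi1 (−0.52 ± 0.10). Cfap54 (0.61 ± 0.11), Pdzd7 (0.41 ± 0.08), BC002163 (0.39 ± 0.07) and Prdm2 (0.33 ± 0.06) went the other way. No member of the fibroblast, red blood cell or interferon lists passed over all genes in limma. Adjusted over the list alone, 16 of 21 fibroblast genes (median −1.17, camera adjusted p = 9.72e-17), 6 of 7 red blood cell genes (median −2.04, 2.82e-08) and 12 of 26 interferon genes (median −0.41, 1.28e-12) had a lower effect in libraries labelled knockout. In the same order, adjusted p = 0.267, 0.159 and 0.267 with an estimated correlation, and 16, 6 and 17 genes were lower at an unadjusted p under 0.05. On the endothelial and mural cell lists 9 and 7 genes were lower at that unadjusted level, against 0 and 1 higher. Fibroblast genes had a positive median in WT after CSDS (0.47), where 1 was called higher and 0 lower. The counts over all genes depended on single libraries, since without WT control 10 the effect was lower for 13 fibroblast, 3 red blood cell and 5 interferon genes, and without WT CSDS 3 for 5 red blood cell genes. With the conflicting libraries as control it was lower for 4 red blood cell genes. Of the 36 lists 22 passed with camera, 2 with fry and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. Heat shock genes had a median difference of 0.11 (camera adjusted p = 7.2e-05; adjusted p = 0.267 with an estimated correlation), and immediate early genes did not pass (camera adjusted p = 0.149). The count of 27 was 1 with the 3 libraries of conflicting label as CSDS and 98 with them as control, and it was 16 without WT control 9, 17 without knockout-label CSDS 1, 68 without WT control 8 and 244 without WT control 10.

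The baseline comparison asked how libraries labelled knockout differ from WT without defeat. Gabra2 (ENSMUSG00000000560, chromosome 5, 70957597 to 71095849), a subunit of the GABA-A receptor, was at 49.0 ± 6.02 RPKM in WT and 23.2 ± 1.84 in libraries labelled knockout (−1.06 ± 0.09, limma adjusted p = 0.00073). Cort (chromosome 4, 149125034 to 149126763), which encodes the interneuron peptide cortistatin, was at 2.38 ± 0.558 and 5.99 ± 0.978 RPKM (1.19 ± 0.14, adjusted p = 0.00572). Nnt, the mitochondrial transhydrogenase, was at 4.18 and 2.93 RPKM (−0.45 ± 0.05, adjusted p = 0.00444), and Bdnf, a neurotrophin, was higher by 0.24 ± 0.04 (adjusted p = 0.014).

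Higher in libraries labelled knockout at baseline were also Zfp982 (1.63 ± 0.27), the near-identical copies Tmem254a, Tmem254b and Tmem254c (1.21 ± 0.08 for Tmem254c, adjusted p = 0.000163), Plac9b (1.20 ± 0.18) and Plac9a (1.19), Pisd-ps1 (1.1), Pisd-ps2 (0.94), Crocc (0.71), Arhgef19 (0.68 ± 0.10) and Mfap2 (0.65 ± 0.10). Lower were Tmem181c-ps (−1.05), Tmem181b-ps (−0.75) and Tmem181a (−0.59 ± 0.05), which can share reads, Snord14c (−0.84), Cfap54 (−0.63), Necab3 (−0.59 ± 0.06), BC002163 (−0.39), Padi2 (−0.39) and the prohormone convertase gene Pcsk1 (−0.37). On the list of endoplasmic reticulum stress 3 genes rose, also adjusted over the list alone where 7 others fell, and the median was −0.12 (camera adjusted p = 0.00204; adjusted p = 0.515 with an estimated correlation). The 3 were Chac1 (0.56 ± 0.06, adjusted p = 0.0042), Atf4 (0.32, adjusted p = 0.0106) and Asns (0.24), of which Atf4 encodes the transcription factor of the amino acid response and the others are among its known targets. Interferon genes had a median of 0.28, with 1 of 26 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 7.6e-07; adjusted p = 0.515 with an estimated correlation). Of 26 immediate early genes, 1 (Bdnf) was higher and 2 lower, 1 and 5 adjusted over the list alone (camera adjusted p = 0.000984; adjusted p = 0.515 with an estimated correlation), with Fosb at −0.31 ± 0.05 (limma adjusted p = 0.0288).

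At baseline 209 of 18297 genes passed (limma-trend), 148 higher and 61 lower in libraries labelled knockout, with 2806 at an unadjusted p under 0.05. Of the lists 18 passed with camera, 1 with fry and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05. Within 10 Mb of Nrsn2, 6 of 231 genes tested passed, against 2.6 expected (Fisher's exact p = 0.0498), while after CSDS 1 of 225 did (Apmap, −0.15, named after its value was seen), against 4.3 expected (p = 0.137). Without WT control 9 the count was 68, without 6 or 7 it was 101 and 115, without knockout-label control 8, 9, 6 or 7 it was 103, 118, 126 and 131, and with the conflicting libraries taken as controls it was 978. Distance between 2 libraries was the median squared difference over genes, relative to counting noise. It was 1.93 for WT control 9 and 9B and 2.67 for 11 and 10B, where all pairs ranged from 1.81 to 11.49. WT CSDS 1 and 5, both in the main test, gave the 1.81, and WT control 6 and 9, also in the main test, gave 2.0. Whether such libraries share an animal was not tested, so the 978 may rest on libraries that are not independent. The same doubt holds for the main counts and p-values of every comparison that uses these WT libraries.

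**Figure D4:**
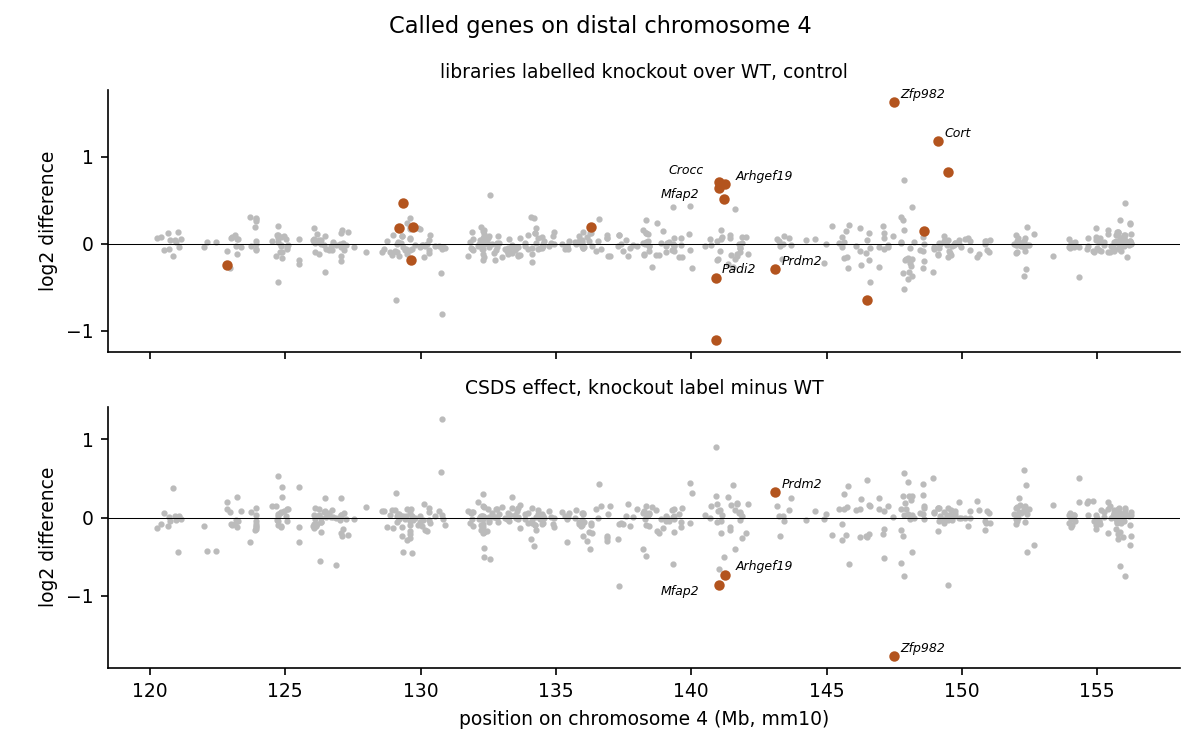
Log2 fold change by position on distal chromosome 4 from 120 Mb on, for libraries labelled knockout over WT among controls (top) and for the difference of the CSDS effect (bottom), a point per gene, with genes past adjusted p = 0.05 in brown. Called genes gather between about 141 and 149 Mb, among them Mfap2 (0.65 and −0.86) and Zfp982 (1.63 and −1.77).

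After CSDS the same genotype comparison was made in the defeated groups. The chemokine genes Ccl21b (chromosome 4, 42255767 to 42256432) and Ccl21a were at 0.130 ± 0.170 and 0.0963 RPKM in WT and at 13 ± 1.75 and 6.52 RPKM in libraries labelled knockout (4.44 ± 0.15 and 3.56 ± 0.07, limma adjusted p = 1.83e-08 and 1.85e-10). They are near-identical copies, and WT controls held 3.92 ± 3.45 and 2.06 RPKM. Gabra2 was again lower, 50.4 ± 2.82 against 17.9 ± 0.547 RPKM (−1.47 ± 0.04, adjusted p = 1.34e-09), Cort higher (1.02 ± 0.08, adjusted p = 2.96e-05), Nnt lower (−0.71 ± 0.08, adjusted p = 0.00143) and Bdnf higher (0.21, adjusted p = 0.0365). Ndn, an imprinted gene of neurons, was at 109 RPKM in WT and 65.9 in libraries labelled knockout (−0.72 ± 0.07, adjusted p = 0.000168).

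Also higher after CSDS in libraries labelled knockout were mt-Tg (1.45 ± 0.09), Mir2139 (0.88), Gstm6 (0.86), the copies Fam205a3, Fam205a2, Fam205a4 and Fam205a1 (0.81, 0.81, 0.80 and 0.67) and the copies Entpd4 and Entpd4b (0.71). Lower were Hbb-bt (−2.01), Hbb-bs (−1.99), Wdfy1 (−0.84), Tmem181b-ps (−0.80), Adi1 (−0.76), Pisd-ps1 (−0.66), Pisd-ps2 (−0.65) and the matrix genes Ogn (−0.93) and Lum (−0.77). Of 21 fibroblast genes 5 were lower, 20 adjusted over the list alone, with a median of −0.60 (camera adjusted p = 3.78e-15; adjusted p = 0.601 with an estimated correlation), among them Dcn (−0.40) and Col1a1 (−0.42). The count of 5 was 2 without knockout-label CSDS 2, 10 without knockout-label CSDS 3 and 1 with the conflicting libraries as CSDS. Of 7 red blood cell genes 2 were lower, 6 adjusted over the list alone (camera adjusted p = 2.86e-05; adjusted p = 0.601 with an estimated correlation), and WT CSDS 3 held the highest haemoglobin. That count was 5 without WT CSDS 3, and 0 with the conflicting libraries as CSDS or without any one of WT CSDS 1, 4 and 5 and knockout-label CSDS 1 to 4. Among 26 myelin genes 1 rose (Trf, 0.37 ± 0.05), 7 adjusted over the list alone (camera adjusted p = 5.23e-05; adjusted p = 0.601 with an estimated correlation). On the list of endoplasmic reticulum stress 4 of 23 genes were higher, also adjusted over the list alone where 1 other was lower (camera adjusted p = 0.979). They were Atf4 (0.36 ± 0.03, limma adjusted p = 0.000122), Chac1 (0.50) and Asns (0.30), called at baseline too, and Sesn2 (0.17), which was at 0.07 there and did not pass. Sgk1 was at −0.44 (adjusted p = 0.0724) and Nrsn2 at 0.20 (adjusted p = 0.123), neither past the threshold.

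After CSDS 349 of 18225 genes passed (limma-trend), 200 higher and 149 lower in libraries labelled knockout. Of the lists 13 passed with camera, 0 with fry and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05. Without knockout-label CSDS 1, 2 or 4 the count was 210, 220 and 219, and without WT CSDS 1, 4 or 5 it was 228, 205 and 231.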

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

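The tests of GC content and gene length, of structural RNAs, of crowding along chromosomes, of the libraries with high Xist and of the allele were chosen only after the results were seen, while the tests on splits of the libraries and on mislabelled libraries were set before.

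Chance was tested with 100 splits of the libraries for each comparison. In each of the 5 comparisons 1 of 100 splits, the real one, gave as many genes. That is the smallest share 100 splits can give, so it argues against chance without excluding it. For the difference of effects, genotype labels were exchanged within condition. A real difference between groups adds to the spread within the other splits, so their low counts were partly set in advance. The real counts were 4093 for CSDS in WT, 2747 in libraries labelled knockout, 27 for the difference, 209 at baseline and 349 after CSDS, against highest other counts of 6, 4, 2, 7 and 17.

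The lower immediate early, heat shock and endoplasmic reticulum stress genes after CSDS are the first pattern. Removing GC and length trends left all 55 members called lower in WT and all 36 called lower in libraries labelled knockout, which argues against those trends as the cause. The mean of 7 structural RNAs without a poly(A) tail was lower in the same groups, but within groups the mean of the 3 lists changed by 0.013 for each log2 unit of structural RNA (95% interval −0.049 to 0.075), where 0.264 in WT and 0.171 for the knockout label would be needed to account for the difference. A time of day or handling at collection that differed between control and defeated mice may lie behind the pattern, since Dbp and Ciart rose with it in both genotypes, and no label gives the time of collection, so this was not tested. An effect of defeat itself stays open as well, untested against collection.

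The second pattern is the crowding of genotype differences on distal chromosome 4. Of the 27 genes with a different CSDS effect, 5 gene families, Arhgef19, Mfap2, Prdm2 and Zfp982 among them, lay within 10 Mb, where random sets of equal size had a median of 2 in their fullest 10 Mb and a 95th percentile of 3 (permutation p = 0.0011 over 10000 sets); at baseline 11 gene families lay between 140906344 and 149501008 (median 6, 95th percentile 8, p = 0.005 over 1000 sets). This is consistent with a strain variant that differs between the WT controls and the other groups, a candidate explanation. Cort, in the same region, and Gabra2 and Nnt, known to carry variants of the C57BL/6J substrain on other chromosomes, did not follow that grouping, since Cort was higher (1.19 and 1.02) and the others lower in libraries labelled knockout at baseline and after CSDS, and none passed for CSDS in WT (adjusted p = 0.206, 0.693 and 0.0991). Among knockout-labelled libraries Gabra2 ranged from 21.4 to 26.2 RPKM in controls and from 17.4 to 18.5 after CSDS, and that fall passed. The control libraries with high Xist were argued against as the source of the 27 genes, since without them 27 of the 27 remained called, while further genes passed as well. For CSDS in WT and in libraries labelled knockout, crowding was tested on only 200 genes each, where 4093 and 2747 were called. Among those 200 it was not beyond random sets in WT (8 families, permutation p = 0.071) or for the knockout label (5 families, permutation p = 0.97). Crowding of all genes called for CSDS was not tested. Between genotypes after CSDS, crowding of 331 genes was not beyond random sets either (8 families, permutation p = 0.75). An effect of the Nrsn2 allele on the genes of this second pattern was not tested.

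The third pattern is that Nrsn2 was not lower in libraries labelled knockout. Of 58 genes that differed between genotypes both at baseline and after CSDS, 100% placed WT 9B, 98.3% placed library 11 and 96.6% placed library 10B nearer to their labelled genotype, which argues against single mislabelled libraries among these 3 but not against exchanged names of whole genotypes. An allele that leaves a transcript counted at gene level may give the ratio of 1.11, and without values per exon it cannot be told apart from an intact gene.

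Single libraries far from the other 4 of their group were flagged in 46 of 528 tests, each of a gene, a list or the depth in a group. Chance gives about 1 in 20 for a single test. The 46 cannot be set against that share, since copies and related genes repeat a flag. Genes not reported here were also dropped from the 46 but not from the 528. In RPKM, WT control 8 stood apart for Zfp982 (1.17 against 0.0440 to 0.220), Mir132 (1.81 against 4.27 to 5.39), Muc3a (3.64 against 2.59 to 2.82) and Cfap54 (1.02 against 1.46 to 1.59). WT control 6 did so for Ttr (16.9 against 1476 to 4740) and S100a10 (8.18 against 7.12 to 7.38), and WT control 7 for Mir129-1 (2.24 against 0.835 to 1.14) and Mir2139 (1.72 against 2.78 to 3.22). WT control 10 was high for Pisd (18.2 against 15.6 to 16.0), Olfml3 (3.36 against 2.78 to 2.90), Gstm6 (4.85 against 4.15 to 4.30), Fam205a3 (4.14), Fam205a2 (4.15), Fam205a4 (4.06) and Fam205a1 (2.60), and low for Gabra2 (38.6 against 48.8 to 53.1).

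After CSDS in WT, library 3 was high for the red cell genes Hbb-bs (676 against 142 to 182), Hbb-bt (668 against 133 to 175), Hba-a2 (801 against 152 to 187), Hba-a1 (654 against 129 to 155) and Alas2 (8.26 against 1.41 to 1.73), with a mean log2 level of the red blood cell list of 7.46 against 5.82 to 5.98. Library 5 of that group was high for Ccl21b (0.434 against 0.0471 to 0.0659) and Lum (4.65 against 3.15 to 3.53), and library 2 for the striatum list (2.42 against 2.03 to 2.14).

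Among knockout-labelled controls, library 10 was high for Gkn3 (3.08 against 1.93 to 2.17) and BC002163 (93.2 against 79.8 to 82.9), and for the lists of endoplasmic reticulum stress (4.31 against 4.16 to 4.20), respiratory chain (6.10 against 5.82 to 5.88) and ribosomal proteins (6.70 against 6.42 to 6.47), and low for NMDA and metabotropic receptors (3.10 against 3.27 to 3.28). Fkbp5 was high in library 9 (11.4 against 8.64 to 9.12) and Crocc in library 8 (12 against 8.73 to 9.26), while library 7 was low for Entpd4 and Entpd4b (11.9 against 16.0 to 16.9) and for the clock list (3.17 against 3.26 to 3.29). In knockout-labelled CSDS libraries, number 3 was low for Mir132 (0.267 against 1.04 to 1.46), AMPA receptor genes (4.55 against 4.60 to 4.62) and interneuron markers (3.39 against 3.48 to 3.5) and high for Alox12b (3.51 against 1.95 to 2.33). Number 5 was low for Glp1r (1.29 against 2.00 to 2.28) and high for BC002163 (85.4 against 77.5 to 79.1) and the respiratory chain (6.01 against 5.93 to 5.95), and number 4 was high for Plac9b (5.60 against 3.52 to 4.00) and low for Entpd4 (13.4 against 17.4 to 18.5) and Entpd4b (13.4).

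A CSDS effect that differed between genotypes was found by the interaction test for these named genes, given as log2 differences, knockout label minus WT. Positive were mt-Tg (1.07), Cfap54 (0.61), Pdzd7 (0.41), BC002163 (0.39) and Prdm2 (0.33). Negative were Zfp982 (−1.77), Pisd-ps1 (−1.74), Pisd-ps2 (−1.59), Tagln (−1.20), Ifit3b (−0.86), Mfap2 (−0.86), Wdfy1 (−0.81), Adi1 (−0.74), Arhgef19 (−0.73), Pisd (−0.71), Olfml3 (−0.52) and Sfi1 (−0.52).

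The libraries of conflicting label, used in no comparison across genes, held signals above the knockout-labelled controls. Mean log2 levels in library 11 were 2.53 for stress neuropeptides (controls 2.42 to 2.47), 3.2 for mossy cells (3.06 to 3.10) and 2.47 for striatum (1.99 to 2.14), and library 10B had 3.19 for mossy cells and 2.48 for striatum. The striatum list shares 3 genes with the stress neuropeptide list and 1 with the mossy cell list, and the last pair shares 2. These levels are therefore not separate signals, and which shared genes carry them was not tested.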

How the results depend on the processing

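Removing GC and length trends, limma-voom on rebuilt reads and leaving out both libraries with high Xist were chosen after seeing the data, and the other settings before. Of the values of named genes under all settings, 12197 kept their side of the threshold, 712 lost the call, 265 gained it and 0 reversed. A change of direction was counted only for genes called in the main fit, so uncalled genes near 0 may have changed sign. The conflicting libraries taken as CSDS ended 118 of these calls. The cause was not tested for any change below. With those 3 libraries as CSDS, the count of genes was 1240 in WT, 143 for the knockout label and 1 for the difference of effects, and r between genotypes was 0.35. With them as control, the difference gave 98, the baseline comparison 978 and r 0.468. The difference also gave 41 without the variance trend, 172 with array weights, 69 with voom and 181 without both libraries of high Xist. At a mean RPKM of at least 1, r was 0.471. With an estimated correlation 0 lists passed in all 5 comparisons (3, 5, 4, 1 and 1 at an unadjusted p under 0.05 for the knockout label, WT, the difference, baseline and after CSDS), and fry passed 7 for the knockout label, 2 for the difference, 1 at baseline and 0 after CSDS. Adding the libraries by treatment field at baseline, or by title after CSDS, changes no library and has no value.

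Leaving out each library in turn gave 3077 to 4016 genes in WT, 1658 to 3668 for the knockout label, 16 to 244 for the difference, 68 to 218 at baseline and 205 to 478 after CSDS, and r of 0.353 to 0.487. For the knockout label the count was 1658 without CSDS 4. The difference was 16 without WT control 9, 17 without knockout-label CSDS 1, 68 without WT control 8 and 244 without WT control 10. Baseline counts were 101, 115 and 68 without WT control 6, 7 and 9, and 126, 131, 103 and 118 without knockout-label control 6, 7, 8 and 9. After CSDS they were 228, 205 and 231 without WT CSDS 1, 4 and 5, and 210, 220 and 219 without knockout-label CSDS 1, 2 and 4.

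The numbers in the titles were not taken to pair libraries across genotypes, since not every pair deviated together: deviations of same-numbered libraries correlated at 0.21, −0.087, 0.304, −0.107 and 0.371 for controls 6 to 10 and at −0.005, 0.097, 0.023, 0.036 and 0.012 for CSDS 1 to 5, and 4 of 10 correlated best with their own number. With the number as a block the counts were 23 for the difference, 45 at baseline and 162 after CSDS, and 42 values of named genes lost their call. Depth was 25.62 M reads in the shallowest library and was not tested as a limit by itself, and at the spread of these libraries the self-test recovered 48% of the smallest simulated differences of effects.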

Other observations

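The counts over tRNA synthetases, the genes Mthfd2, Ide, Xist and Ddx3y, and the rise or fall of markers in the left-out libraries were chosen after their values were seen.

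Cars, Yars, Nars and Gars, which encode enzymes that charge tRNAs in the cytosol, were higher in libraries labelled knockout at baseline and after CSDS, at 0.24 ± 0.04 and 0.30 ± 0.04, 0.18 ± 0.03 and 0.16 ± 0.02, 0.16 ± 0.03 and 0.24 ± 0.02, and 0.14 ± 0.02 and 0.17 ± 0.02, while Hars was lower (−0.22 and −0.15). Of 20 such synthetase genes 4 were higher and 1 lower at baseline, and 6 were higher and 1 lower after CSDS. Of 17 mitochondrial synthetase genes 1 was higher at baseline and 0 after CSDS. The class was chosen because of its called members, so no test of it is given. With CSDS 7 of the 20 cytosolic genes rose in WT and 7 in libraries labelled knockout, and 6 and 1 of the 17 mitochondrial ones did, while 1 of these fell in libraries labelled knockout (Lars2, −0.88 ± 0.27, adjusted p = 0.0495). Mthfd2, a folate enzyme of mitochondria, was higher by 0.40 ± 0.06 at baseline (limma adjusted p = 0.0139) and by 0.39 ± 0.06 after CSDS (adjusted p = 0.00663).

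The 3 libraries titled control with CSDS in the treatment field had these values, in the order WT 9B, knockout-labelled 11 and 10B. Fosb was at 2.87, 2.22 and 2.21 RPKM, where WT libraries ranged from 2.72 to 3.26 in controls and 0.923 to 1.08 after CSDS, and knockout-labelled libraries from 2.10 to 2.49 and 0.772 to 0.878. Fos was at 4.16, 3.06 and 3.33 RPKM, where CSDS libraries reached at most 2.18 in WT and 1.76 for the knockout label. Homer1 was at 12.3, 11.6 and 10.3, where CSDS libraries reached at most 8.47 and 7.65. Hsph1 was at 48.5, 45.8 and 46.8, where CSDS libraries reached at most 38.1 and 39.6. Dbp was at 12.5, 10.5 and 10.3 RPKM, with WT controls at 10.4 to 13.6 and WT after CSDS at 19.7 to 23.4, and knockout-labelled libraries at 9.29 to 11.0 and 18.8 to 21.2. For Fosb, Fos, Homer1, Hsph1 and Dbp, all 3 libraries lay outside the CSDS range of their genotype, on the side of the controls. Hspa5 was at 99.9, 74.0 and 74.8 RPKM, with WT controls at 92.5 to 121 and WT after CSDS at 55.1 to 67.8, and knockout-labelled libraries at 78.9 to 97.8 and 50.3 to 60.6, so that 11 and 10B lay between the ranges of their genotype. n-R5-8s1 was at 15.3, 112 and 15.2 RPKM, where the ranges in the same order were 31.6 to 159, 13.1 to 32.1, 21.4 to 273 and 7.85 to 22.9, which puts WT 9B and 10B below the controls and within the CSDS libraries. Ttr was at 1460, 62.8 and 66.5 RPKM, against 16.9 to 4740, 2800 to 3610, 552 to 4380 and 481 to 3640. Ide, the insulin-degrading enzyme, was at 18.4, 16.8 and 17.0 RPKM. WT controls ranged from 8.71 to 17.4 and WT after CSDS from 8.47 to 9.05, so WT 9B lay above both. Knockout-labelled libraries ranged from 8.10 to 12.6 in controls and from 8.49 to 13.6 after CSDS, so 11 and 10B lay above both.

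Xist, which is expressed from the inactive X chromosome of females, was at 56.5 RPKM in WT control 10 and 48.2 in knockout-labelled control 10, where the Y-linked gene Ddx3y was at 0.163 and 0.499 RPKM. Xist was at most 0.0543 RPKM in WT after CSDS and 0.0618 in knockout-labelled libraries after CSDS. The female pattern was thus found in a library of each control group and in no CSDS library. Libraries 11 and 10B had 1.60 and 1.45 RPKM of Xist with Ddx3y at 9.99 and 8.75. Ccl21a and Ccl21b were spread widely among WT controls (2.06 ± 1.78 and 3.92 ± 3.45 RPKM) and narrowly among knockout-labelled controls (4.95 ± 0.529 and 10.0 ± 0.692).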
